A study of Mus musculus with 47 samples.

How the data were processed

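The processed intensities deposited by the authors were used as they were. The authors' notes name lumi and limma without versions or roles. The values themselves show what had been done to the deposited intensities. Negative values point to a subtracted background, and nearly identical sorted values within 39 arrays and within the other 8 point to quantile normalization in 2 separate sets. Between 31.2% and 32.1% of the values of an array were under 1. The labels call the replicates biological triplicates. KO EpiLC arrays 2 and 3 were close but not identical (r = 0.995). If they came from 1 culture, KO EpiLC would have 2 independent samples.

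Values under 1 were set to 1, log2 was taken, and the arrays of each fit were quantile-normalized again. A means model with 1 coefficient per group was fitted to each set in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with a constant prior), so that all groups of a set shared the spread. Probes with a Benjamini-Hochberg adjusted p under 0.05 over all 25697 probes were called. The comparison of the CHIR99021 response between the 2 media used 1 fit of the 47 arrays with contrasts inside each set. Of the probes, 23978 carried 1 gene symbol and 1719 none, which gave 16593 genes. For a gene with several probes the one with the highest mean was used. The mouse assembly table GRCm38.p6 served for names and chromosomes. The comparisons, the main settings and most alternatives were chosen before the data were examined.

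The 16 gene lists held 209 genes, 191 of them measured, and were written beforehand. They cover TCF/LEF factors, naive pluripotency, general pluripotency, formative and primed genes, Wnt/beta-catenin targets, primitive streak and mesendoderm, neural genes, FGF/ERK feedback, LIF/Stat3 targets, germline and methylation-sensitive genes, 2-cell-like genes, p53 and stress, glycolysis and hypoxia, and markers of extraembryonic endoderm, trophoblast and fibroblasts. Each list was tested in each of 25 comparisons with camera from limma at a preset correlation of 0.01, adjusted over the 400 tests, and again with an estimated correlation. Of 129 list calls, 90 held with the estimated correlation, and an adjusted p after a list is that of camera. Direction in camera, median and mean differed in sign for 1 list, the Wnt targets in the KO response. Tcf7, Tfcp2l1, T and 15 other listed genes had no named probe.

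A gene counted as below background in a group when all its arrays lay under the size of the lowest value of the set, 13.6 or 14.3. Where 1 side was below, the fold is given as at least the other side over the limit, and where both were, none is given. Genes named outside the lists came from the 10 largest called changes in each direction. After the data were seen, that ranking was narrowed to differences measured above background on both sides.

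The chromosome test took genes with a mean intensity over 100. It compared, within each condition, the median of each chromosome between the 9 arrays of a line and the 9 WT arrays by exact permutation of labels, with adjustment over 60 tests. It was added after the data were seen. The 2 conditions with 1 array each were ranked against 10000 random lists without a test of single genes.

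On simulated values with known changes the same code recovered 56.9% of 1.5-fold, 69.4% of 2-fold and 93.7% of 4-fold changes for 3 against 3 arrays, with 18 calls among 25497 unchanged probes. For a difference of 2 responses these were 34.4%, 66.7% and 91.4%, with 45 calls. The changed probes were drawn only from the 11574 with a mean above background, so recovery among dimmer probes was not measured. The 1 shifted list was called and none of the other lists, and a chromosome shifted by 0.5 log2 was read as 0.50, with at most 0.04 for the others. Noise was drawn separately for each probe, so false list calls that come from correlation between genes could not appear.

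Alternatives were cyclic loess, no second normalization, a floor at the background limit, leaving out the dimmest 33.3% of probes, trended and robust eBayes, a block for the replicate number, the spread of the compared groups alone, all 47 arrays in 1 fit, 1 probe per gene, fry in place of camera, genes of chromosomes 1 and 6 left out, KO EpiLC arrays 2 and 3 averaged, and each array left out in turn. No array was left out of the main results. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Unnormalized intensities, detection p values and slide positions were not analysed here.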

Results

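Gene expression was measured on 47 Illumina mouse arrays with 25697 probes each, in embryonic stem (ES) cells of 4 lines. Besides the wild type (WT), these were a line without Tcf7l1 (KO), a line without Tcf7, Tcf7l2 and Lef1 (3XKO) and a line without all 4 TCF/LEF factors (4XKO), the DNA-binding partners of beta-catenin in Wnt signalling. Each line was grown as naive ES cells with 1 uM PD0325901 (a MEK inhibitor), 3 uM CHIR99021 (a Gsk3 inhibitor) and 1000 U/mL LIF (ESC), as epiblast-like cells with 12 ng/mL Fgf2 (EpiLC), and as EpiLC given 3 uM CHIR99021 for 24 hours after 3 days in Fgf2 (EpiLC+CH). No time in Fgf2 was recorded here for untreated EpiLC, so any difference in days of culture is not told apart from CHIR99021 in EpiLC+CH. WT cells were also grown with Fgf2 and CHIR99021 from the start (ContinuedCH). These 13 groups had 3 arrays each. The labels name 1 line per genotype, so a p value against WT measures the spread between arrays of a line. A lost factor is not told apart from other differences between the lines, such as the chromosome shifts described below. A separate set of 8 WT arrays covered LIF+PD (3 arrays), LIF+PD followed by CHIR99021 (3 arrays), LIF+CH (1 array) and PD+CH (1 array). Levels below are mean intensities ± SD of 3 arrays, and differences of log2 values are given ± SE. The series title asks how Tcf7l1 ties the naive pluripotency genes to the response to Gsk3 inhibition.

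Between 44.5% and 44.6% of probes lay above the background limit of 13.6 in the 39 arrays, and 42.7% to 42.8% lay above 14.3 in the 8 arrays. Replicates correlated at r = 0.982 to 0.995 across probes in the first set and 0.979 to 0.988 in the second, probes not being independent replicates. Of the 45 arrays with replicates, 43 were closest to an array of their own group. The exceptions were replicate 1 of KO EpiLC+CH and replicate 1 of 4XKO EpiLC+CH, each closest to an untreated EpiLC array of its line. Tcf7l1 was lower in the lines that lack it, at 194 ± 20.1 in KO ESC and 681 ± 55.1 in 4XKO ESC against 1499 ± 191 in WT. In EpiLC it stood at 704 ± 34.8 in KO and 836 ± 107 in 4XKO against 2018 ± 22.0 in WT, so a signal above background stayed. Lef1 was 27.6 ± 4.57 in 3XKO EpiLC and 68.6 ± 5.11 in WT EpiLC. Tcf7l2 was low in all lines and was not called between 3XKO and WT, at 78.7 ± 1.80 against 88.9 ± 12.3 in ESC. The labels do not say which exons were deleted, and Tcf7 had no named probe. The TCF/LEF list holds Tcf7l1, Tcf7l2 and Lef1, the factors deleted in the mutant lines. Its calls between lines can follow from the deletions alone and are not read as a response of the list.

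The comparison of WT EpiLC with ESC asked which genes change as cells leave the naive state. Genes of naive pluripotency fell. Tcl1, a co-activator of Akt, dropped from 1786 ± 117 to 45.2 ± 7.38 (39.8-fold), and the nuclear receptor gene Nr5a2 from 1013 ± 96.0 to 27.9 ± 6.10 (36.8-fold). Klf2 and Klf4, transcription factor genes of the naive network, were 27.1-fold and 24.3-fold lower, and Tbx3 was at least 106-fold lower. Of the 17 measured naive genes, 12 fell, 2 rose (Gbx2 and Dppa3) and 3 were not called, with 15 called when adjusted over the list alone (adjusted p = 2.98e-12). Formative and primed genes rose, 12 of 16 (12 adjusted over the list alone, adjusted p = 9.24e-08). Among them were the DNA methyltransferase gene Dnmt3b, from 1087 ± 66.7 to 14394 ± 988, the transcription factor gene Otx2 (5.34-fold), Fgf5 (at least 64.5-fold) and Pou3f1 (at least 194-fold).

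Lists of signalling targets were tested in the same comparison, in which PD0325901, CHIR99021, LIF and Fgf2 all differ between the media. FGF/ERK feedback genes rose, with 8 of 15 higher (9 adjusted over the list alone, adjusted p = 0.000178). Dusp6, an ERK phosphatase gene, rose from 568 ± 27.1 to 2999 ± 237, and Egr1 and Etv4 rose 16.2-fold and 3.57-fold. LIF/Stat3 targets fell, 7 of 10 (7 adjusted over the list alone, adjusted p = 0.00106), among them Socs3 (9.60-fold), Bcl3 (14.1-fold) and Stat3 (3.40-fold). The list of Wnt targets as a whole was not called (adjusted p = 0.161), with 7 of 18 members lower, such as Notum (11.7-fold), Cdx1 (10.3-fold) and Axin2 (8.48-fold), and 3 higher. Primitive streak genes leaned lower (7 of 20, with 2 higher, adjusted p = 0.0392 and adjusted p = 0.101 with an estimated correlation), with Lefty2 10.8-fold and Nodal 6.01-fold lower and Lefty1 8.44-fold higher. Fibroblast markers rose in 3 of 9 members (adjusted p = 0.0246). These were Acta2, which encodes smooth muscle actin, at 2522 ± 99.3 from below background, Thy1 and Dcn, while 6 members such as the collagen genes stayed below background. The remaining lists were not called: TCF/LEF factors (adjusted p = 0.332), general pluripotency (adjusted p = 0.126), neural (adjusted p = 0.752), germline and methylation-sensitive (adjusted p = 0.635), 2-cell-like (adjusted p = 0.655), extraembryonic endoderm (adjusted p = 0.168), trophoblast (adjusted p = 0.327), p53 and stress (adjusted p = 0.892), and glycolysis and hypoxia (adjusted p = 0.0604).

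In all, 7714 of 25697 probes differed between WT EpiLC and ESC, 4037 higher and 3677 lower. Among the largest rises on both sides of which signal was measured were Gadd45g, a growth arrest gene (144-fold), the splicing regulator gene Esrp1 (111-fold) and Etv2 (33.3-fold). Among the largest falls were S100a13 (65.2-fold), the riboflavin transporter gene Slc52a3 (57.4-fold) and the transcription factor gene Msc (48.5-fold).

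**Figure D1:**
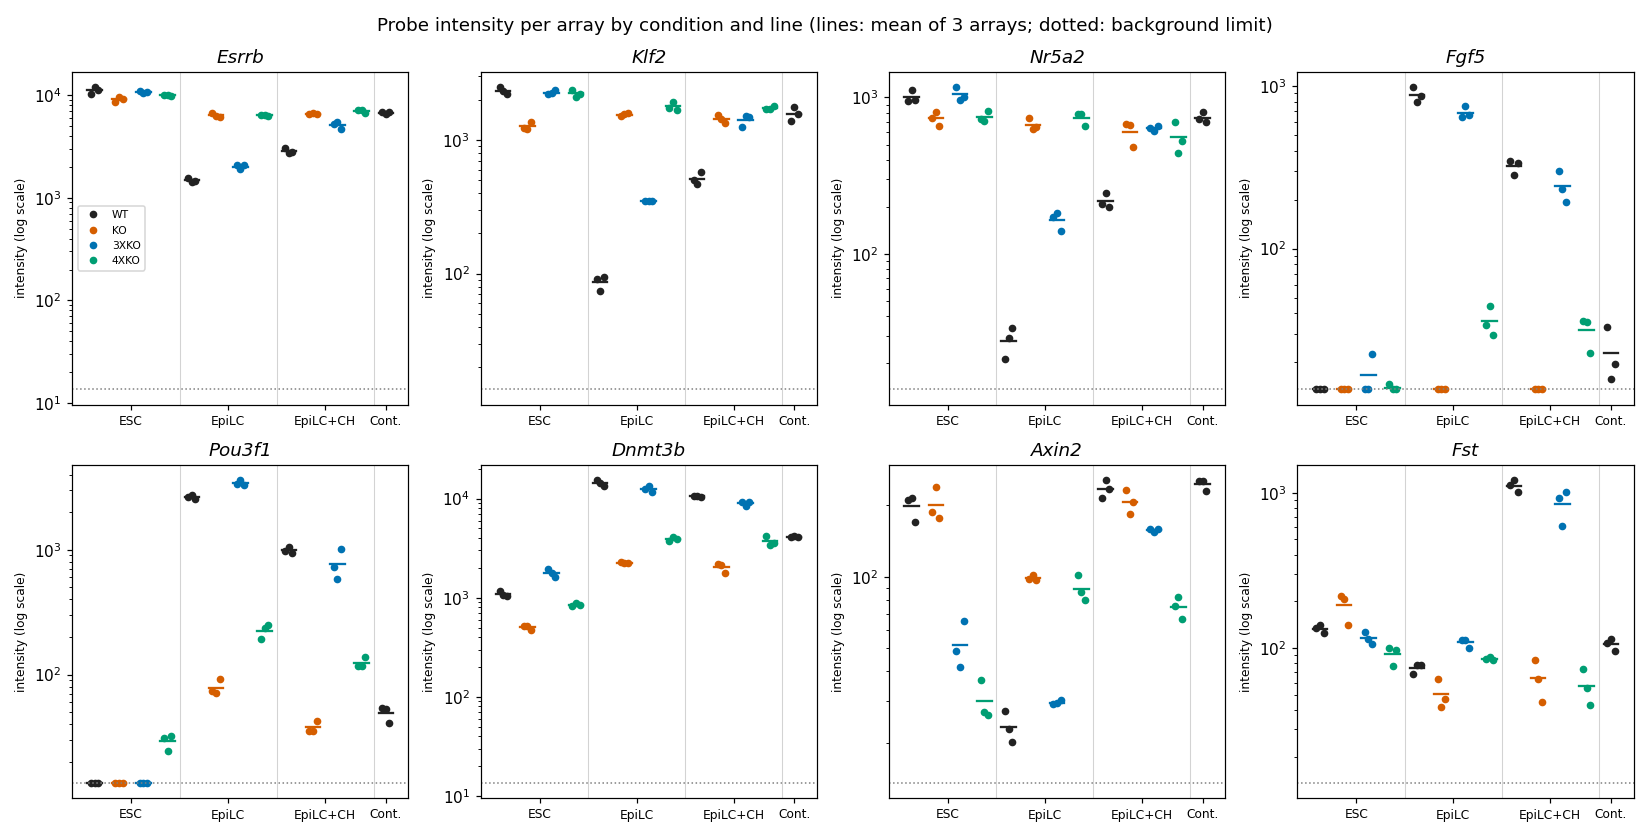
Probe intensity (log axis, no unit) of 8 genes on each array, by condition on the x axis and line in colour, with "Cont." for WT ContinuedCH. Points are arrays, bars are means of 3, and values under the background limit of 13.6 (dotted) are drawn at it. Klf2 was 86.7 ± 10.5 in WT EpiLC against 1545 ± 40.7 in KO and 1786 ± 122 in 4XKO EpiLC.

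The next question was what Gsk3 inhibition does to cells that have left the naive state. CHIR99021 given to WT EpiLC for 24 hours raised naive genes and Wnt targets. Fst, which encodes the activin antagonist follistatin, rose from 74.4 ± 5.57 to 1112 ± 99.2 (14.9-fold). Axin2, a feedback inhibitor of Wnt signalling, rose from 23.4 ± 3.63 to 234 ± 20.5 (10.1-fold), Tnfrsf19 14.3-fold, and the transcription factor gene Sp5 rose from below background to 988 ± 157. Nr5a2 and Klf2 rose 7.94-fold and 5.94-fold, and Tcl1 4.22-fold. Of the naive genes 13 of 17 rose and 2 fell (15 adjusted over the list alone, adjusted p = 7.38e-21), the falls being Gbx2 (3.52-fold) and Fgf4 (2.10-fold). Levels of Klf2 and Nr5a2 stayed under those of ESC, 514 ± 52.5 against 2338 and 219 ± 24.5 against 1013. Wnt targets rose in 6 of 18 members, with 1 lower (7 adjusted over the list alone, adjusted p = 5.67e-07). Primitive streak and mesendoderm genes rose in 9 of 20 (9 adjusted over the list alone, adjusted p = 6.75e-11), including Wnt8a (at least 20.8-fold), Evx1 (at least 5.27-fold), Fgf8 (at least 4.56-fold) and Nodal (4.71-fold).

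Formative genes fell in 4 of 16 members after CHIR99021 in WT EpiLC (7 adjusted over the list alone, adjusted p = 0.000157): Sall2 (4.21-fold), Krt18 (3.46-fold), Otx2 (1.48-fold) and Dnmt3b (1.36-fold). Extraembryonic endoderm markers fell in 3 of 11 (6 members below background, adjusted p = 0.00787), namely the laminin gene Lama1 (5.95-fold), Dab2 and Sparc, genes that other cells express too. Outside the lists, the thyrotropin-releasing hormone gene Trh rose from 658 ± 44.8 to 6986 ± 597, Nt5e rose 34.7-fold and Rasgrp1 10.3-fold, while the phospholipase gene Plcd1 fell 12.5-fold and the neurogenic factor gene Insm1 5.82-fold. The count was 1674 probes, 838 higher and 836 lower, and 780 when the spread was estimated from the compared groups alone.

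The KO, 3XKO and 4XKO responses asked which factors this needs. Without Tcf7l1 the response to CHIR99021 in EpiLC was small. Axin2 rose from 98.6 ± 2.67 to 207 ± 24.5 in KO cells (2.09-fold), Tnfrsf19 2.32-fold, Cdx1, a homeobox Wnt target, 3.21-fold, and Sp5 at least 18.6-fold. With these 4 of 18 Wnt targets higher, the list was called upward (5 adjusted over the list alone, adjusted p = 0.0119), although its median was -0.10 and its mean 0.35 log2. None of the 17 naive genes passed in limma over all probes, with 1 adjusted over the list alone (adjusted p = 0.315), and Klf2 was 1437 ± 109 against 1545 ± 40.7 without it. In the streak list 1 rose and 1 fell (Cdx2 and Lefty1). General pluripotency genes shifted down by a median of -0.23 log2 (1 of 11 lower, adjusted p = 0.003), FGF/ERK feedback genes by -0.20 (0 of 15 called, adjusted p = 0.0131) and formative genes by -0.23 (1 of 16 lower, adjusted p = 0.0182 and adjusted p = 0.0724 with an estimated correlation). Of the other genes, Pglyrp1, a peptidoglycan recognition gene, rose 3.85-fold, the focal adhesion gene Zyx 2.04-fold and Uap1l1 2.01-fold, and the P-cadherin gene Cdh3 fell 2.41-fold. The 240 called probes (94 higher and 146 lower) became 26 with the spread of the compared groups alone (Axin2 adjusted p = 0.0751) and 101 with KO EpiLC arrays 2 and 3, the closest pair of replicates, averaged as if they were 1 sample. They ranged from 113 to 237 as arrays were left out in turn.

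In 3XKO EpiLC, which keep Tcf7l1, CHIR99021 raised 10 naive genes of 17 and lowered 2 (14 adjusted over the list alone, adjusted p = 5.45e-13). Klf2 rose from 351 ± 0.635 to 1417 ± 149 (4.03-fold), Nr5a2 3.87-fold and Tbx3 3.84-fold. Wnt targets rose in 5 of 18 (adjusted p = 0.000103), with Axin2 5.32-fold and Tnfrsf19 5.21-fold higher. Streak genes rose in 8 and fell in 1 of 20 (11 adjusted over the list alone, adjusted p = 7.88e-11), with Fst 7.61-fold and Lefty2 4.91-fold higher. Formative genes fell in 5 of 16 (8 adjusted over the list alone, adjusted p = 1.39e-05), with Pou3f1 4.57-fold and Sall2 4.44-fold lower. General pluripotency (4 of 11 lower, adjusted p = 0.0217) and extraembryonic endoderm markers (3 of 11 lower, adjusted p = 0.013) shifted down, the latter through Lama1 (2.79-fold), Dab2 and Sparc. Trh and Nt5e rose 5.09-fold and 9.45-fold, and the Notch ligand gene Dll1 fell 6.64-fold. Of the 838 probes raised in WT and the 764 raised in 3XKO, 409 were shared, where 24.9 would be expected by chance. Of the lowered, 387 were shared against 24.1, with no array in common. These and later chance values treat all probes as equally likely to be called, also those below background, and are therefore rough. The count was 1504 probes, 764 higher and 740 lower, and 551 with the spread of the compared groups alone.

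Without all 4 factors, CHIR99021 left Wnt targets uncalled. Axin2 was 74.9 ± 7.96 against 89.2 ± 11.3 without it and Sp5 24.5 ± 10.1 against 16.0 ± 2.41 in 4XKO EpiLC. In limma 0 of 18 Wnt targets and 0 of 20 streak genes rose, with 0 and 7 called in either direction when adjusted over the list alone (adjusted p = 0.351 and adjusted p = 0.0521). The naive list was not called either (adjusted p = 0.819). TCF/LEF factors fell in 2 of 3 (adjusted p = 0.000785, but adjusted p = 0.115 with a floor at the background limit), both dim, with Tcf7l2 going from 43.0 ± 11.7 to 25.7 ± 3.70. General pluripotency genes shifted by a median of -0.20 log2 (0 of 11 called, adjusted p = 0.0389 and adjusted p = 0.0587 with an estimated correlation). Still, 555 probes changed, 221 higher and 334 lower. Uap1l1 and Renbp, genes of amino sugar metabolism, rose 2.19-fold and 1.96-fold, Bhlhe40 rose 1.88-fold, and the D-type cyclin gene Ccnd2 fell from 618 ± 64.5 to 279 ± 77.9. Uap1l1 and Renbp also rose in KO cells, by 2.01-fold and 1.84-fold. The KO and 4XKO responses shared 29 raised and 65 lowered probes, where 0.808 and 1.90 would be expected by chance. Overlap with WT was present too, with 39 raised and 63 lowered probes shared by KO (3.07 and 4.75 expected). For 4XKO and WT these were 38 and 61 (7.21 and 10.9 expected). Another 39 probes raised in WT were lowered in 4XKO, and 12 lowered in WT were raised. The count fell to 44 with the spread of the compared groups alone, and ranged from 182 to 522 as arrays were left out in turn.

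**Figure D2:**
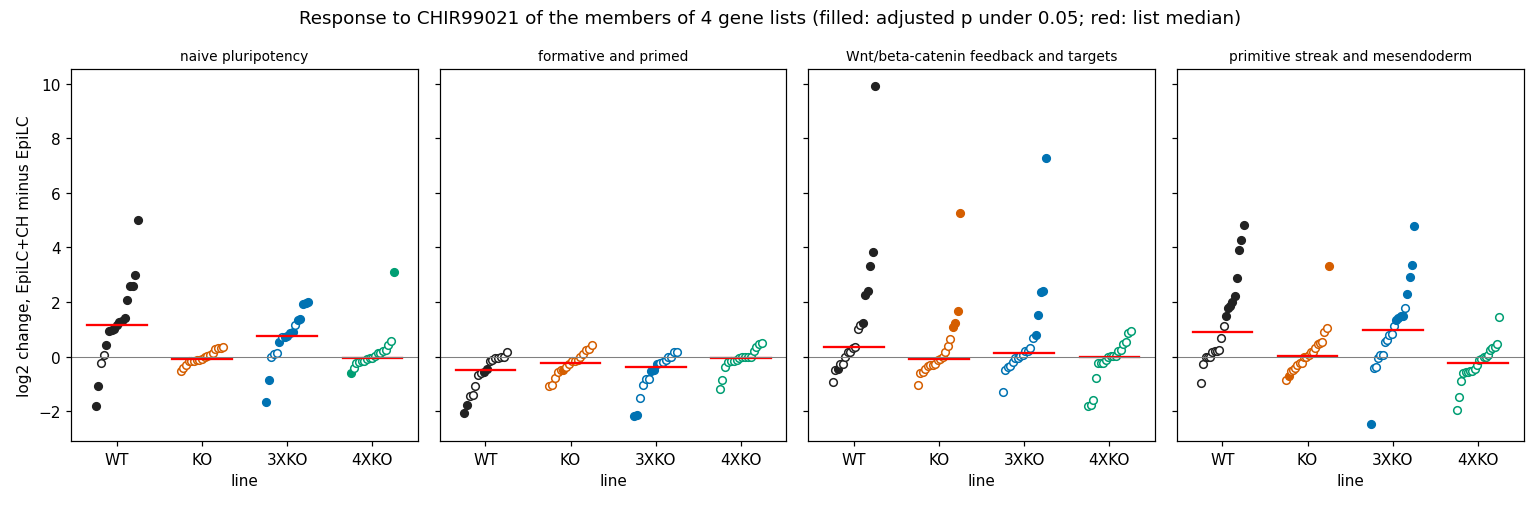
Log2 change with CHIR99021 (EpiLC+CH minus EpiLC, y axis) of the measured members of 4 gene lists in the 4 lines (x axis). Each point is a gene from 3 against 3 arrays, filled at an adjusted p under 0.05, and the red bar is the list median. Changes of genes below background in a group depend on the floor of 1. The naive median was 1.17 in WT, -0.11 in KO, 0.77 in 3XKO and -0.05 in 4XKO.

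The differences between these responses were tested directly. The lines did not start level, since most naive genes and Axin2 were already higher in untreated KO and 4XKO EpiLC than in WT EpiLC. Klf2 in both untreated lines even exceeded its level in WT EpiLC+CH. A weaker response therefore does not show by itself that CHIR99021 cannot raise these genes without the lost factors. Against WT, the KO response was weaker for 12 naive genes (15 of 17 called adjusted over the list alone, with 1 higher, adjusted p = 4.73e-23), with Nr5a2 at -3.15 ± 0.23 log2 and Klf2 at -2.68 ± 0.13. It was weaker for 7 streak genes (adjusted p = 1.97e-09) and 5 Wnt targets (adjusted p = 5.7e-06), with Fst at -3.59 ± 0.29 and Axin2 at -2.26 ± 0.21. Downward differences were also found for FGF/ERK feedback genes (2 of 15 lower, adjusted p = 0.0306), with Egr1 at -2.30 ± 0.28. Extraembryonic endoderm markers leaned upward (1 of 11 higher, adjusted p = 0.045 and adjusted p = 0.0673 with an estimated correlation), through Lama1 at 3.40 ± 0.14. The 4XKO response was weaker than that of WT for 13 naive genes (with 1 higher, adjusted p = 2.33e-16), 8 streak genes (adjusted p = 2.85e-10) and 6 Wnt targets (adjusted p = 9.24e-08), with Axin2 at -3.58 ± 0.21 and Fst at -4.51 ± 0.29, while formative genes differed upward (3 of 16 higher, adjusted p = 0.00946), with Krt18 at 2.01 ± 0.49. Called probes numbered 523 for KO minus WT and 1115 for 4XKO minus WT.

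For 3XKO minus WT the differences were fewer, 178 probes. Wnt targets responded less (3 of 18, adjusted p = 0.00208, but adjusted p = 0.27 with a floor at the background limit), with Axin2 at -0.92 ± 0.21 and Tnfrsf19 at -1.46 ± 0.25 log2. So did the naive list (3 lower and 1 higher of 17, adjusted p = 1.88e-07), with Nr5a2 at -1.04 ± 0.23 and Esrrb at 0.40 ± 0.09. Most naive genes, Nr5a2 among them, were already higher in untreated 3XKO EpiLC than in WT EpiLC, so this line did not start level either. FGF/ERK feedback genes (2 of 15 lower, adjusted p = 0.0297), germline genes (0 of 12 called, adjusted p = 0.0321 and adjusted p = 0.0574 with an estimated correlation) and p53 and stress genes (1 of 11 lower, adjusted p = 0.0159 and adjusted p = 0.19 with an estimated correlation) also leaned lower, the last with Cdkn1a at -0.81 ± 0.15. Bmp4 differed by 1.32 ± 0.14. Between 4XKO and KO, 13 probes differed (1 higher and 12 lower), and with arrays left out in turn 8 (1 higher and 7 lower) to 30 (18 higher and 12 lower) did. Axin2 (-1.31 ± 0.21), Pglyrp1 (-2.17 ± 0.26), Zyx (-0.90 ± 0.14) and Dclk3 (-1.37 ± 0.24) differed downward in 4XKO. In the list tests Wnt targets leaned lower (2 of 18 members, adjusted p = 9.53e-05), as did TCF/LEF factors (1 of 3 lower, adjusted p = 0.00966 and adjusted p = 0.0905 with an estimated correlation) and streak genes (0 of 20 called, adjusted p = 0.0265 and adjusted p = 0.0751 with an estimated correlation), and glycolysis genes leaned higher (0 of 11 called, adjusted p = 0.00524 and adjusted p = 0.113 with an estimated correlation). With the spread of the compared groups alone these counts were 62 for 3XKO minus WT and 2 for 4XKO minus KO. With a floor at the background limit they were 422 and 23, and 839 for KO minus WT.

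The untreated lines were compared with WT EpiLC to see how each differs without CHIR99021. In both lines without Tcf7l1, naive genes were high and formative genes low in EpiLC. In KO EpiLC, Tcl1 was 1438 ± 108 against 45.2 ± 7.38 in WT (32.0-fold), Nr5a2 24.4-fold higher, Klf2 17.9-fold, Dppa3 16.5-fold and Esrrb 4.29-fold. Dppa3 was already higher in KO ESC, and its change from ESC to EpiLC differed from that of WT by only 0.75 ± 0.20 log2. Of 17 naive genes, 13 were higher and 1 lower, Gbx2 (14 adjusted over the list alone, adjusted p = 4.53e-18). Of 16 formative genes, 10 were lower (11 adjusted over the list alone, adjusted p = 4.95e-09), such as Fgf5 (at least 64.5-fold), Pou3f1 (33.9-fold) and Dnmt3b (6.35-fold). The 4XKO EpiLC showed 13 naive genes higher (with 1 lower, adjusted p = 3.32e-19), with Nr5a2 26.9-fold and Klf2 20.7-fold, and 10 formative genes lower (adjusted p = 9.24e-08), with Fgf5 24.8-fold and Pou3f1 11.8-fold. Streak genes were higher in 8 of 20 in 4XKO (adjusted p = 0.00218), such as Lefty2 (10.7-fold) and Bmp4 (4.85-fold), and in 6 in KO with 2 lower (adjusted p = 0.0265 and adjusted p = 0.0751 with an estimated correlation), Lefty2 again being higher (17.3-fold).

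Other groups moved with these in KO, 4XKO or both. Fibroblast markers were lower in KO (3 of 9, adjusted p = 0.0271) and 4XKO (3, adjusted p = 0.0235), through Acta2 (132 ± 10.9 and 134 ± 8.85 against 2522 ± 99.3 in WT), Thy1 and Dcn, 6 members being below background. The p53 and stress list was lower in KO (6 of 11, with 1 higher, adjusted p = 0.0058 and adjusted p = 0.138 with an estimated correlation) and 4XKO (4, with 2 higher, adjusted p = 0.0182 and adjusted p = 0.202 with an estimated correlation). Its falling members included the stress genes Trib3 (5.82-fold in KO) and Ddit3 (3.69-fold), while Cdkn1a, the p21 gene, was 1.55-fold higher. Glycolysis and hypoxia genes were lower in 4XKO (6 of 11, with 1 higher, adjusted p = 0.0102 and adjusted p = 0.141 with an estimated correlation), such as Ldha (2.24-fold) and Slc2a1 (2.73-fold). TCF/LEF factors were lower in KO (2 lower and 1 higher of 3, adjusted p = 0.0354 and adjusted p = 0.165 with an estimated correlation) and 4XKO (2 of 3 lower, adjusted p = 0.00687 and adjusted p = 0.0756 with an estimated correlation). This list holds the deleted factors themselves. Called probes were 5600 in KO (2865 higher and 2735 lower) and 5135 in 4XKO (2646 higher and 2489 lower). Outside the lists, the cartilage matrix gene Crtac1 was 36.3-fold higher in KO and 26.1-fold in 4XKO, Gsta3 24.3-fold and 26.5-fold, and the chemokine gene Cxcl12 was 24.6-fold and 23.8-fold lower.

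The 3XKO EpiLC, with Tcf7l1, lay closer to WT in formative genes (1 higher and 2 lower of 16, adjusted p = 0.275), with Fgf5 at 687 ± 61.2 against 880.5 ± 98.0 in WT. Naive genes were nonetheless higher in 13 of 17 (adjusted p = 4.53e-18), with Nr5a2 5.97-fold and Klf2 4.07-fold. Klf2 stood below its level in KO (351 ± 0.635 against 1545 ± 40.7), but 3XKO and KO were not tested against each other. Germline and methylation-sensitive genes were higher in 5 of 12 (7 adjusted over the list alone, adjusted p = 0.000303), such as Dazl (5.35-fold) and Asz1 (5.29-fold), both needed for germ cells. Wnt targets were higher in 5 of 18 (with 1 lower, adjusted p = 0.0214, but adjusted p = 0.0547 without the dimmest probes), trophoblast markers in 3 of 10 (4 below background, adjusted p = 0.0134 and adjusted p = 0.113 with an estimated correlation), among them Tfap2c (3.38-fold) and Gata3 (4.55-fold). Glycolysis and hypoxia genes were lower in 7 (with 1 higher, adjusted p = 8.29e-05), such as Pfkl (2.73-fold) and Aldoa (2.22-fold). The largest rises were in Magea2 (21.4-fold), Magea5 (17.6-fold) and Ott (16.0-fold), testis-expressed genes, and the largest falls included the actin gene Acta1 (12.5-fold), Aldoc (8.85-fold) and Pdlim3 (7.10-fold). The count was 4822 probes, 2482 higher and 2340 lower.

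As naive ES cells the lines differed from WT by 2412 (KO), 3644 (3XKO) and 1453 (4XKO) probes. In KO ESC the collagen IV genes Col4a2 and Col4a1 were 7.13-fold and 5.53-fold higher and Dppa3 9.81-fold, while Gpnmb was 15.4-fold and Bmp4 5.25-fold lower. Naive genes leaned slightly lower in KO (6 lower and 1 higher of 17, the latter Dppa3, adjusted p = 0.00634), such as Klf2 (1.85-fold), as did Wnt targets (3 lower and 1 higher, adjusted p = 0.03, but adjusted p = 0.077 with that floor) and formative genes (2 lower and 1 higher of 16, adjusted p = 0.0409 and adjusted p = 0.12 with an estimated correlation). TCF/LEF factors, a list that holds the deleted Tcf7l1, were lower too (1 of 3 lower, adjusted p = 0.00154). Extraembryonic endoderm markers were higher in 4 of 11 (adjusted p = 0.0374 and adjusted p = 0.0573 with an estimated correlation), such as Gata6 (3.00-fold) and Sparc (1.47-fold). In 3XKO ESC germline genes were higher in 4 of 12 (adjusted p = 0.001), such as Asz1 (3.18-fold). The p53 and stress list was higher (3 of 11 higher, adjusted p = 0.0056 and adjusted p = 0.137 with an estimated correlation), with Ddit3 3.41-fold, and glycolysis genes were lower (2 of 11 lower, adjusted p = 0.0193 and adjusted p = 0.174 with an estimated correlation), with Pfkl 1.57-fold. Magea2 (10.8-fold) and Nlrp4c (12.1-fold) were higher, and Axin2 was 3.86-fold lower.

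The 4XKO ESC had low Wnt targets despite CHIR99021 in the medium. Sp5 was 18.8 ± 6.99 against 301 ± 14.4 in WT (16.9-fold), Axin2 30.0 ± 5.97 against 198 ± 24.2 (6.64-fold), Tnfrsf19 5.01-fold lower and Cdx1 4.32-fold, 6 of 18 members (8 adjusted over the list alone, adjusted p = 1.04e-07). Naive genes differed little, with 1 of 17 lower and a median of -0.20 log2 (adjusted p = 0.0246), the called gene being Zfp42 (1.35-fold). FGF/ERK feedback genes were higher in 5 of 15 (adjusted p = 0.00129), such as Egr1 (2.14-fold), germline genes in 3 of 12 (adjusted p = 0.0248), and fibroblast markers in 1 of 9, Thy1 (adjusted p = 0.0311 and adjusted p = 0.0522 with an estimated correlation). TCF/LEF factors were lower (1 of 3 lower, adjusted p = 0.00687 and adjusted p = 0.0756 with an estimated correlation). With the spread of the compared groups alone, the counts in ESC were 1224 for KO, 2107 for 3XKO and 464 for 4XKO.

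After CHIR99021 the lines were compared with WT EpiLC+CH. Fst, which rose in WT, was 64.0 ± 19.6 in KO and 57.4 ± 15.4 in 4XKO against 1112 ± 99.2 in WT, and Sp5 was 3.87-fold and 42.3-fold lower. Wnt targets were lower in 7 of 18 in 4XKO (with 1 higher, adjusted p = 0.00256), against 6 in KO (adjusted p = 0.0785). Naive genes were higher, 13 in KO (with 1 lower, adjusted p = 3.25e-12), 12 in 3XKO (adjusted p = 1.98e-14) and 16 in 4XKO (adjusted p = 5.47e-17), such as Tcl1 (9.42-fold, 2.38-fold and 8.30-fold in that order). Formative genes were lower in KO (9, adjusted p = 6.37e-08) and 4XKO (9, adjusted p = 2.37e-05), with Dnmt3b 5.26-fold and 2.85-fold lower. FGF/ERK feedback genes were lower in KO (8, with 1 higher, adjusted p = 0.000137) and 4XKO (6, adjusted p = 0.00852), with Dusp4 6.99-fold and 3.87-fold. Fibroblast markers (4 of 9 lower, adjusted p = 0.0131 in KO, 4 of 9 lower, adjusted p = 0.00958 in 4XKO) and p53 and stress genes (7 of 11 lower, adjusted p = 1.36e-05, 6 of 11 lower, adjusted p = 0.000121) were lower too, with Acta2 30.8-fold and 29.0-fold. The fibroblast calls ended with a floor at the background limit (adjusted p = 0.0611 and adjusted p = 0.0758). General pluripotency genes were lower in KO (5 lower and 1 higher of 11, adjusted p = 0.0202), and TCF/LEF factors in KO (2 lower and 1 higher of 3, adjusted p = 0.0258 and adjusted p = 0.142 with an estimated correlation) and 4XKO (2 of 3 lower, adjusted p = 0.000381).

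In 3XKO EpiLC+CH germline genes (5 higher and 1 lower of 12, adjusted p = 0.00978) and extraembryonic endoderm markers (5 of 11 higher, adjusted p = 0.0098, or adjusted p = 0.0643 with that floor, and Gata6 5.26-fold) were higher, and glycolysis genes lower (8 lower and 1 higher of 11, adjusted p = 0.00144 and adjusted p = 0.0724 with an estimated correlation). The cardiac actin gene Actc1 was 81.6-fold lower. Called probes were 5411 in KO, 4525 in 3XKO and 5305 in 4XKO, and 2759 in 3XKO with the spread of the compared groups alone.

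The change from ESC to EpiLC itself was compared between lines. A difference in this change can come from the ESC level as well as from the EpiLC level. Axin2, for instance, was below WT in 3XKO and 4XKO ESC. Naive genes differed upward from WT, for 13 genes in KO (with 1 lower, adjusted p = 1.25e-18), 14 in 3XKO (adjusted p = 3.73e-23) and 13 in 4XKO (with 1 lower, adjusted p = 2.11e-22) of 17. For Nr5a2 the change differed by 5.08 ± 0.23, 2.53 ± 0.23 and 5.18 ± 0.23 log2, and for Klf2 by 5.05 ± 0.13, 2.07 ± 0.13 and 4.44 ± 0.13. Formative genes differed downward in KO (8 of 16, with 1 higher, adjusted p = 4.22e-05) and 4XKO (8, adjusted p = 9.24e-08), with Dnmt3b at -1.55 ± 0.12 and -1.53 ± 0.12, while in 3XKO the list was not called (adjusted p = 0.494). Wnt targets differed upward in all 3 lines (4 higher and 1 lower of 18, adjusted p = 0.0181 in KO, where a floor at the background limit gave adjusted p = 0.115, 6 of 18 higher, adjusted p = 0.00124 in 3XKO, 7 higher and 2 lower of 18, adjusted p = 0.000661 in 4XKO), with Axin2 at 2.07 ± 0.21, 2.30 ± 0.21 and 4.66 ± 0.21. Streak genes differed upward in KO (7 higher and 1 lower of 20, adjusted p = 0.0248 and adjusted p = 0.0724 with an estimated correlation) and 4XKO (5 higher and 1 lower of 20, adjusted p = 0.00163), such as Nodal (2.00 ± 0.18 and 2.14 ± 0.18).

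Further lists differed in these changes. Glycolysis genes differed downward in KO (5 lower and 1 higher of 11, adjusted p = 0.0127 and adjusted p = 0.148 with an estimated correlation), 3XKO (4 lower and 1 higher of 11, adjusted p = 0.0297 and adjusted p = 0.209 with an estimated correlation) and 4XKO (5 lower and 1 higher of 11, adjusted p = 0.029 and adjusted p = 0.208 with an estimated correlation), with Ldha at -1.57 ± 0.16, -0.67 ± 0.16 and -1.21 ± 0.16. Fibroblast markers differed downward in 3XKO (2 of 9 lower, adjusted p = 0.0312 and adjusted p = 0.0522 with an estimated correlation) and 4XKO (3 of 9 lower, adjusted p = 0.00309), p53 and stress genes in KO (7 lower and 1 higher of 11, adjusted p = 0.00218 and adjusted p = 0.107 with an estimated correlation), with Trib3 at -2.79 ± 0.35, and FGF/ERK feedback genes in 4XKO (4 lower and 1 higher of 15, adjusted p = 0.0341 and adjusted p = 0.054 with an estimated correlation), with Ier3 at -2.82 ± 0.32. Trophoblast markers differed upward in 3XKO (2 of 10 higher, adjusted p = 0.0131 and adjusted p = 0.113 with an estimated correlation), with Tfap2c at 2.14 ± 0.12. Called probes were 4249 for KO, 2715 for 3XKO and 3695 for 4XKO.

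ContinuedCH asked whether Gsk3 inhibition from the start acts differently. It differs from EpiLC+CH in both the onset and the length of CHIR99021 treatment. The ESC medium holds CHIR99021 as well, so onset, length and a period without the inhibitor are not told apart. WT cells given CHIR99021 together with Fgf2 from the start had higher naive genes than EpiLC. Tcl1 was 1382 ± 186 against 45.2 ± 7.38 in EpiLC (30.6-fold), Nr5a2 27.0-fold, Klf2 18.1-fold and Esrrb 4.53-fold higher, 13 of 17 naive genes (15 adjusted over the list alone, with 1 lower, adjusted p = 1.53e-18). Formative genes were lower in 11 of 16 (adjusted p = 1.23e-09), with Pou3f1 54.0-fold, Fgf5 40.6-fold and Dnmt3b 3.47-fold. Wnt targets were higher in 6 of 18 (with 2 lower, adjusted p = 0.0181), such as Notum (12.6-fold) and Axin2 (10.5-fold), and streak genes in 7 of 20 (adjusted p = 8.29e-05), such as Lefty2 (17.3-fold) and Bmp4 (4.22-fold). FGF/ERK feedback genes (7 lower, with 1 higher, adjusted p = 0.00208), fibroblast markers (3 of 9 lower, adjusted p = 0.00702), glycolysis genes (7 lower and 1 higher of 11, adjusted p = 0.00242 and adjusted p = 0.0866 with an estimated correlation) and p53 and stress genes (7 lower and 2 higher of 11, adjusted p = 0.00927 and adjusted p = 0.158 with an estimated correlation) were lower, with Dusp4 13.6-fold, Acta2 18.4-fold, Slc2a1 2.71-fold and Atf3 13.5-fold.

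Against cells that met CHIR99021 as EpiLC, the continuous treatment gave higher naive genes (13 of 17, with 1 lower, adjusted p = 6.44e-14), with Jam2 10.2-fold and Tbx3 8.31-fold, and lower formative genes (10, adjusted p = 7.6e-08), with Pou3f1 20.2-fold. The streak list was not called (adjusted p = 0.895), but Fst was 106 ± 9.21 against 1112 ± 99.2 in EpiLC+CH (10.5-fold) and Wnt8a at least 20.8-fold lower, while Lefty2 and Bmp4 were 4.76-fold and 3.77-fold higher. FGF/ERK feedback genes were lower in 9 of 15 (adjusted p = 4.73e-06), such as Egr1 (7.34-fold), as were fibroblast markers (4 of 9 lower, adjusted p = 0.000406), p53 and stress genes (7 of 11 lower, adjusted p = 0.000278 and adjusted p = 0.0568 with an estimated correlation) and glycolysis genes (5 lower and 1 higher of 11, adjusted p = 0.00634 and adjusted p = 0.119 with an estimated correlation). Counts were 4944 probes against EpiLC and 4306 against EpiLC+CH, the latter 2524 with the spread of the compared groups alone.

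The second set asked what CHIR99021 does to cells in LIF+PD, where few probes were called. Axin2 rose from 26.9 ± 8.03 to 319.8 ± 24.1 (12.2-fold), Pglyrp1 from 83.4 ± 21.7 to 908 ± 175, the homeobox gene Gbx2 4.10-fold and Dclk3 4.11-fold. Otx2 fell from 1001 ± 61.7 to 322 ± 23.2 (3.11-fold), Lefty1 2.87-fold, the neural gene Sox21 2.75-fold, and Eras, which encodes an ES cell Ras protein, 4.42-fold. Of the naive genes 1 of 17 rose (adjusted p = 0.827), and Klf2 stood at 3329 ± 203 against 3101 ± 182 before. The Wnt list was called upward (1 of 18, 4 adjusted over the list alone, adjusted p = 0.00184 and adjusted p = 0.12 with an estimated correlation), and general pluripotency (adjusted p = 0.0116 and adjusted p = 0.113 with an estimated correlation) and LIF/Stat3 targets (adjusted p = 0.0386 and adjusted p = 0.162 with an estimated correlation) downward, with no member of either called by limma over all probes and 2 LIF/Stat3 targets adjusted over the list alone. The name of the condition gives 24 hours of CHIR99021 where the growth protocol gives 48 hours after 24 hours in LIF+PD, so its duration is uncertain. The 88 probes (48 higher and 40 lower) became 8 with a floor at the background limit, where none of the genes named here passed (Axin2 adjusted p = 0.0732), and 1182 when all 47 arrays shared the fit. With arrays left out in turn the share of higher probes ran from 22.1% (15 higher and 53 lower) to 81.9% (59 higher and 13 lower).

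The response to CHIR99021 in WT cells differed between LIF+PD and EpiLC. Klf2 already stood at 3101 ± 182 in LIF+PD before CHIR99021, so different starting levels were not separated from different responses. The media also differ in PD0325901, LIF and Fgf2. The time in CHIR99021, uncertain for LIF+PD, may differ as well, and these differences are not told apart. The change of naive genes was lower in LIF+PD (11 of 17 lower, with 1 higher, adjusted p = 3.32e-19), with Nr5a2 at -2.62 ± 0.24 and Klf2 at -2.50 ± 0.13 log2, while Gbx2 was at 3.79 ± 0.14. The change was also lower for streak genes (5 of 20, adjusted p = 6.51e-09), with Fst at -3.58 ± 0.31 and Nodal at -2.36 ± 0.17, and for general pluripotency genes (1 of 11 lower, adjusted p = 0.0235), with Sox2 at -1.63 ± 0.41. The Wnt list was not called (adjusted p = 0.0998). Among the 838 probes raised in EpiLC and 48 raised in LIF+PD, 18 were shared, where 1.57 would be expected by chance, and these included Axin2, the Wnt acyltransferase gene Porcn and the Wnt receptor gene Ror2. This overlap rests on the LIF+PD calls, which changed much with the floor and the fit as given above. Axin2 lost its LIF+PD call with a floor at the background limit. The arrays of the 2 media had been normalized as separate sets, so the test compared 2 changes, each within its own set. It called 606 probes, 283 higher and 323 lower, and 244 with the spread of the compared groups alone or 1075 with a floor at the background limit.

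Genes of chromosomes 1 and 6 shifted together in mutant lines. In 3XKO the 243 genes of chromosome 1 with a mean intensity over 100 had a median log2 difference from WT of 0.50 in ESC, 0.50 in EpiLC and 0.55 in EpiLC+CH, and all 9 arrays lay beyond all WT arrays of their condition (exact permutation within conditions, 2-sided, p = 0.00025, the smallest possible, adjusted p = 0.0015 over 60 tests). Of these genes 74.1% were called higher in ESC, against 14.3% of other genes. The 260 genes of chromosome 6 were lower in 3XKO (-0.21, -0.24 and -0.28 in the same order) and higher in KO (0.18, 0.19 and 0.15), each with the same p. Chromosome 6 was uneven, since with differences averaged over conditions the medians of 10 parts in gene order ran from -0.36 to -0.09 in 3XKO and from 0.02 to 0.30 in KO, against 0.45 to 0.62 for chromosome 1 in 3XKO. In 4XKO the chromosome 1 medians lay between -0.01 and 0.06. Most of the other chromosome tests passed too, but with far smaller shifts, the largest median in a condition being -0.09 for chromosome 14 in 3XKO EpiLC+CH (exact permutation over the 3 conditions, adjusted p = 0.0015). Tcf7l1, Nanog and Dppa3 lie on chromosome 6.

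**Figure D3:**
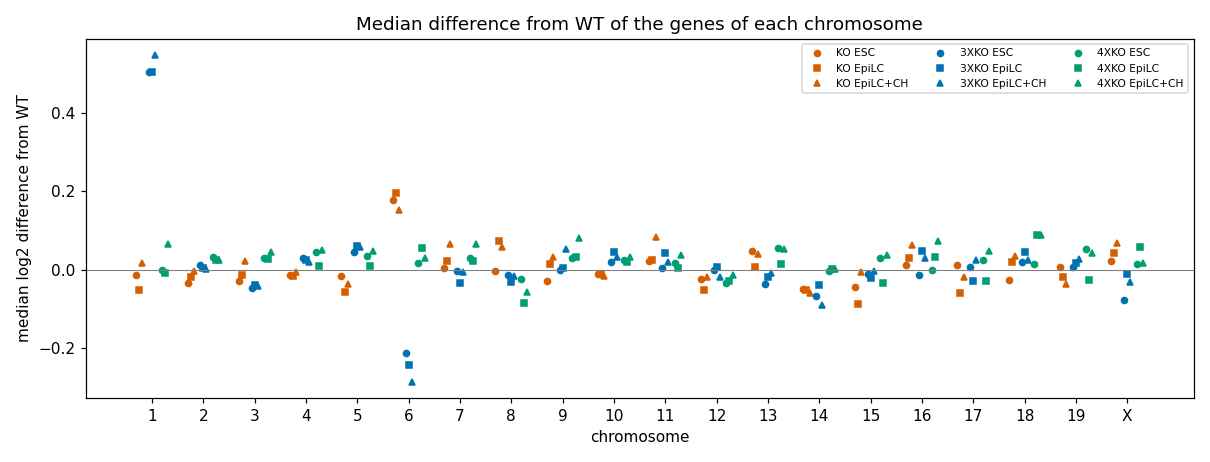
Median log2 difference from WT (y axis) of the genes of each chromosome (x axis) with a mean intensity over 100. Colours are lines and marker shapes are conditions, each from 3 against 3 arrays. Chromosome 1 in 3XKO stands at 0.50 to 0.55.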

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

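The tests of whether other groupings of the same arrays call as many probes were chosen before the results were seen, while the tests on chromosomes, on shared control arrays and on remaining TCF/LEF activity were chosen after. For the comparisons of 3 with 3 arrays the 6 arrays allow 10 splits, too few for a share under 0.05, and in each the real split alone (1 of 10) reached its own count. The real count and the highest of the other splits were 7714 and 10 for WT EpiLC against ESC. For the response to CHIR99021 they were 1674 and 22 in WT, 240 and 5 in KO, 1504 and 11 in 3XKO, 555 and 10 in 4XKO, and 88 and 15 in LIF+PD. Against WT they were 2412 and 15, 5600 and 10, and 5411 and 8 for KO in ESC, EpiLC and EpiLC+CH. For 3XKO they were 3644 and 10, 4822 and 5, and 4525 and 14, and for 4XKO 1453 and 10, 5135 and 2, and 5305 and 25. ContinuedCH gave 4944 and 6 against EpiLC and 4306 and 4 against EpiLC+CH.

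The comparisons of responses were tested with 100 reassignments of residuals, the real one included. KO minus WT called 523 probes, reached in 2 of 100 with 694 as the highest other, and 3XKO minus WT 178, reached in 3 with 243. 4XKO minus WT called 1115 (1, highest other 351) and 4XKO minus KO 13 (2, highest other 16). The change from ESC to EpiLC differed from WT by 4249 probes in KO (2, highest other 4547), 2715 in 3XKO (1, highest other 503) and 3695 in 4XKO (1, highest other 1602). The response in LIF+PD differed from that in EpiLC by 606 (1, highest other 211). An arbitrary grouping of the arrays was thereby excluded for these 8 counts at a share of 0.05.

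In 3XKO the genes of chromosome 1 were higher as a block, by 0.529 log2 on average over conditions, and those of chromosome 6 lower. The lowest of 10 parts of chromosome 1 in gene order was at 0.454, which is consistent with an extra copy of the whole chromosome in these cells. Brightness or normalization was excluded, since genes of other chromosomes matched on level were at 0.0104. Loss of Tcf7, Tcf7l2 and Lef1 came without such a shift in 4XKO, which lacks them too, with chromosome 1 at 0.0211. As 4XKO is another line and also lacks Tcf7l1, an effect of that loss that needs Tcf7l1 was not excluded. DNA copy number was not analysed here, and a cause for chromosome 6 stays open.

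Genes changed by loss of Tcf7l1 in EpiLC changed alike under continuous CHIR99021 in WT. Shared control arrays were excluded as the source, since 4XKO minus 3XKO correlated with ContinuedCH minus EpiLC at r = 0.638 across 7284 genes, with no array in common. An incomplete change from ESC to EpiLC alone stays open. The 2893 genes not called in that change gave r = 0.368, over the 0.3 set beforehand for excluding it, but a rank correlation of 0.261, which was asked to pass too only after both values were seen, and the 4391 called genes gave r = 0.698. Leaving out called genes does not remove changes too small to call, and in the 2893 genes 4XKO minus 3XKO still correlated with ESC minus EpiLC in WT at r = 0.138. Genes are not independent replicates, so these values carry no p. Whether inhibition of Gsk3 may act by way of Tcf7l1 here (r = 0.638) stays open, as the arrays hold no protein or binding data.

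In 4XKO EpiLC 555 probes changed with CHIR99021. Of these, 85.9% moved the same way in KO, where 56.4% did in 3XKO and 55.1% in WT, so an array effect of the 4XKO samples alone was excluded. Remaining TCF/LEF activity was excluded as far as Axin2 reports it, since the upper 95% limit of the change of Axin2 was 0.0556 log2. An effect of Gsk3 inhibition outside TCF/LEF might explain the 85.9%. A difference of culture, time in Fgf2 included, or of hybridization common to KO and 4XKO could do so as well and stays open.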

How the results depend on the processing

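Cyclic loess, no second normalization, the dimmest 33.3% of probes left out, trended and robust eBayes, and 1 probe per gene left every count within 1.5-fold. The quantile alternative equals the main choice. Slide as a block and normexp were not run, as slides and unnormalized values were not analysed here. The floor at the background limit, the averaging of 2 arrays, the omission of chromosomes and the fit without a second normalization were chosen after the data were seen.

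With the spread of the compared groups alone, counts fell. The responses to CHIR99021 gave 780 in WT, 26 in KO (7 higher and 19 lower), 551 in 3XKO and 44 in 4XKO. The differences gave 62 for 3XKO minus WT (18 higher and 44 lower), 2 for 4XKO minus KO (1 each way) and 244 for LIF+PD minus EpiLC. Against WT, ESC gave 1224 for KO, 2107 for 3XKO and 464 for 4XKO, EpiLC+CH gave 2759 for 3XKO, and ContinuedCH against EpiLC+CH gave 2524. Fewer arrays leave fewer degrees of freedom.

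With a floor at the background limit, KO minus WT gave 839, 3XKO minus WT 422, 4XKO minus KO 23 (9 higher and 14 lower), LIF+PD minus EpiLC 1075, and CHIR99021 in LIF+PD 8 (6 higher and 2 lower). The cause was not tested. As 44.5% to 44.6% of probes lie above the background limit, changes of the dimmer genes are known only as limits.

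CHIR99021 in LIF+PD gave 1182 with all 47 arrays in 1 fit. With the replicate number as a block limma gave 0, with 1753 at an unadjusted p under 0.05, where camera still called the Wnt targets. The block moved no other count beyond 1.5-fold. Numbers were not taken to pair samples: in 17 comparisons checked, residuals of equal numbers correlated at -0.261 to 0.246, none had all pairs over 0.1, and in 2 every array correlated best with its own number. Leaving out an array kept the count at 59 to 82, but the share of higher probes went from 22.1% (15 higher and 53 lower) without an array of LIF+PD to 81.9% (59 higher and 13 lower) without one given CHIR99021. No gene named for it kept its call with the floor at the background limit.

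Leaving out arrays in turn moved 3 results. The 4XKO response ranged from 182 to 522, with 182 and 266 without EpiLC arrays 2 and 3, and 246 and 330 (175 higher and 155 lower) without EpiLC+CH arrays 2 and 3. The KO response ranged from 113 to 237, with 114 and 129 without EpiLC arrays 2 and 3, and 151 and 113 without EpiLC+CH arrays 2 and 3. 4XKO minus KO ranged from 8 to 30, with 8 without KO EpiLC array 2 and 28, 22 and 30 without 4XKO EpiLC+CH arrays 1, 2 and 3. Averaging KO EpiLC arrays 2 and 3, which correlate at r = 0.995 and whose values are not identical, gave 101 for the KO response and 8 for 4XKO minus KO.

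Fry, which asks whether any shift exists and not whether it exceeds that of other genes, gave 251 list calls against 129. Leaving out arrays gave 125 to 132. Without chromosomes 1 and 6 the share of probes called in 3XKO went from 14.2% to 13.1% in ESC, 18.8% to 18.1% in EpiLC and 17.6% to 16.9% in EpiLC+CH. No called gene named here turned its direction.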

Other observations

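The 2 media with 1 array each can be described but not tested gene by gene, since they have no replicates. Both hold CHIR99021, which LIF+PD lacks, so a shift from LIF+PD need not come from the missing LIF or PD0325901 alone. With PD+CH, the medium without LIF, LIF/Stat3 targets had a median of -1.68 log2 against the mean of the LIF+PD arrays, lower than all 10000 random lists of the same size. Socs3, a feedback inhibitor of LIF signalling, read 32.6 against 1507 ± 78.2 in LIF+PD (3 arrays), Bcl3 17.6 against 199 ± 10.8, and Klf4 107 against 349 ± 79.4. The naive list stood at -0.50 log2, Wnt targets at 0.83 and streak genes at 0.52, with Axin2 at 424 against 26.9 ± 8.03. Many streak genes and several Wnt targets lay under the limit of 14.3 in both media, such as Wnt3 (-1.07 and 7.2), so these medians depend on the floor. Measured streak genes went both ways, Lefty1 reading 2547 against 1286 ± 158 and Gsc 14.4 against 165 ± 13.8. Extraembryonic endoderm markers stood at -1.12 (percentile 0.01) and p53 and stress genes at -0.66 (percentile 0.065). The endoderm markers Gata4, Gata6, Sox17, Pdgfra, Afp and Ttr lay under 14.3 in LIF+PD, PD+CH and LIF+CH, so their part of the shift depends on the floor. Sox7, Dab2, Amn, Lama1 and Sparc all read lower in PD+CH.

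With LIF+CH, the medium without the MEK inhibitor, FGF/ERK feedback genes had a median of 0.80 log2 (percentile 99.97 of random lists). Etv4 read 1191 against 73.9 ± 17.7 and Dusp6 1934 against 367 ± 79.8. Wnt targets stood at 0.63 (percentile 99.71), extraembryonic endoderm markers at -0.69 (percentile 0.685) and p53 and stress genes at -0.45 (percentile 1.31). The endoderm markers above background did not all fall. Dab2, Amn and Sparc read lower in LIF+CH, Lama1 higher (544 against 318 ± 43.2) and Sox7 about level (30.7 against 30.0 ± 8.47). Tcf7l1 read 895 in LIF+CH, 2552 in PD+CH and 3176 ± 220.2 in LIF+PD, and Gbx2 1059, 95.9 and 146 ± 23.9. LIF+PD then CHIR99021 gave a Tcf7l1 level of 2408 ± 101 (3 arrays). What lowers Tcf7l1 in LIF+CH was not tested, as this medium has 1 array.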
